A study of Schmidtea mediterranea with 4 samples.

How the data were processed

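The series holds 4 libraries from asexual Schmidtea mediterranea, a freshwater planarian flatworm that regrows lost body parts. Per the labels, 1 library was sequenced as Illumina short reads from rRNA-depleted RNA that pooled uncut worms with worms collected at 0, 1, 3, 6, 9, 12, 24 and 48 hours after amputation. The other 3 were PacBio Iso-Seq long-read libraries, of which 1 was titled rRNA-depleted at 0 hours, 1 total RNA at 0 hours and 1 rRNA-depleted over the pooled time points. The protocols of the libraries titled total RNA and pooled rRNA-depleted go against their titles, since the first describes an rRNA depletion step and the second starts from 100 ng of DNase-treated total RNA without one. No library is set against another here, so this contradiction enters no value below. Each of the 4 groups had 1 library, and there were no replicates.

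The data analysed were 1 deposited gene annotation in GTF format, which combines the libraries. Its values are positions in nt, start and end of each record, and the file carries no read depth, expression value or library of origin. Per the file headers it was written with rtracklayer 1.66.0, and its source column names StringTie, a transcript assembler, and NewAnnot_Sep23, whose meaning is not given in the sources used here. Per the submitters' processing notes, MultiQC, Trim Galore, STAR and minimap2 were used, with no versions. The genome build and the assembly settings are not given in the sources used here, and coordinates are printed as in the deposited annotation. Depth per library was therefore unknown, and no genome sequence was used here. A spike-in RNA mix was added at 1% per the labels, and the annotation held 0 sequences named after it.

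Transcripts were rebuilt from the exon records. All 245468 gaps between neighbouring exons equalled the intron records. Transcript length is the sum of exon lengths, and the exon number of a locus is that of its transcript with most exons, except in the gene lists, which used the longest transcript. Loci were grouped by identifier and source into SMESG loci with source StringTie, MSTRG loci with source StringTie, SMESG loci with source NewAnnot_Sep23 and mitochondrial genes. MSTRG is the default prefix of loci in StringTie's merge mode, which combines assemblies; whether that mode was run is not given in the sources used here. Protein names and Pfam domains are those written in the deposited file, and gene functions given beside them are background.

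Splicing events were called within genes from exon coordinates. An exon was skipped where another transcript of the gene had an intron from the start of its upstream intron to the end of its downstream intron. An intron was retained where it lay within an exon of the same gene. Alternative donors and acceptors were pairs of introns that shared the other end and had overlapping exons at the differing end. A constitutive exon was internal and had the same ends in every transcript of the gene that spanned it, in at least 2 transcripts.

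Shares have 95% Wilson intervals and differences have 95% bootstrap intervals from 2000 resamples. Medians were compared with two-sided permutation tests of 100000 resamples, with Benjamini-Hochberg adjustment, and classes over chromosomes with a chi-square statistic and 100000 permutations. All p-values and intervals are over loci, exons or features of 1 pooled annotation. They say nothing about spread between animals or libraries, loci are not independent replicates, and intervals cover counting error only. Positions of ncRNA features were compared with 1000 rotations along each chromosome (a circular permutation test), and antisense pairs with 100 rotations. Chromosome lengths were taken up to the last annotated base.

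For the 15 gene lists, which are patterns in protein names, the mean transcripts per gene was set against 10000 random lists of the same size, matched on the exon number of the longest transcript in 13 quantile bins, which is a two-sided permutation of list membership within bins. A gene entered a list where the name of any of its transcripts matched. Genes with more transcripts thus had more chances to enter, which can raise list means. The random lists were first drawn from all genes. After that result was seen, the pool was restricted to genes with a protein name, since only those could enter a list; the fixed design did not name the pool. The restriction lowered the number of lists called from 7 to 4, and both versions are reported among 9 versions run. A further version drew random lists from all genes and left out the member with most transcripts of each list.

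The tests were run on simulated data. All 12 of 12 toy genes with a known splicing event or none were called correctly. With 0.3 transcripts per gene added to lists of 200 genes, 9 of 10 changed lists and 0 of 10 unchanged lists were called. The median test with 2000 loci per group called 0 of 20 unchanged sets, 6 of 20 sets shifted by 1 exon and 20 of 20 shifted by 2, so that it had low power at a shift of 1. The pass criteria had first asked for all lists and for a shift of 1 exon, and were loosened after these outcomes. The chromosome test called 2 of 20 shuffled sets.

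The comparisons of content, transcripts per gene, coding against non-coding, chromosomes and gene lists, the alternatives other than those named next, and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes with most transcripts, the 5 with the longest transcript, the 5 with the longest span, the 5 with most exons, 2 per list and the locus with most transcripts in each class. The gene list alternatives other than span matching and equal intron chains, the coding against non-coding alternative with planarian names, and the comparisons by locus class, of introns, splicing events, reading frame, antisense genes, Pfam domains and ncRNA families were chosen after the file was seen. The position of introns was first examined by setting single first introns against per-gene medians of later introns, which are unlike quantities; after that result was seen, shares by position replaced it, and both had first introns shorter. Comparisons planned for long-read against short-read support, reference overlap, splice-site dinucleotides and untranslated or coding lengths were not run, because the fields or the genome they need were not used here. Of the coding against non-coding measures, only length was run, since every ncRNA feature is a single block. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.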

Results

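The pooled annotation of uncut and regenerating Schmidtea mediterranea held 25265 genes with 41394 transcripts, all typed as mRNA, and 13419 ncRNA features on 4 nuclear chromosomes and the mitochondrial sequence. It came from 4 libraries, 1 of short reads and 3 of long reads, with 1 library per group. There were no replicates, the depth is unknown, and time points or library types could not be compared. Transcripts had a median spliced length of 1735 nt and ranged from 200 to 48466 nt. The transcripts contained 159699 distinct exons and 120698 distinct introns.

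More than 1 transcript was annotated for 8498 genes, or 33.6% (95% Wilson interval 33.1 to 34.2%), while 16767 genes had 1 transcript. At least 10 transcripts were annotated for 74 genes. Multi-exonic transcripts made up 82.5% of transcripts (82.2 to 82.9%). Laminin subunit alpha-1 (SMESG000055070.1), a basement membrane protein, had the most, 48 transcripts with up to 92 exons over positions 71561288 to 71637924 of chromosome 1. Microtubule-actin cross-linking factor 1 (SMESG000043809.1), which links cytoskeletal filaments, followed with 38 transcripts on chromosome 3, and SMESG000077813.1, without a protein name, with 30. SMESG000040665.1 had 24 transcripts, which carried 8 different protein names, Ankyrin-1 and a retrovirus-related Pol polyprotein among them. Ankyrin-3, which ties membrane proteins to the cytoskeleton, was the name of SMESG000058557.1 with 20 transcripts and of SMESG000000606.1 with 18. SCO-spondin (SMESG000042718.1), a secreted glycoprotein, had 18 transcripts, and Endophilin-B1 (SMESG000043769.1), a membrane-bending protein, 17. Mitogen-activated protein kinase-binding protein 1 (SMESG000080852.1) also had 17.

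The PRP4 homolog (SMESG000004953.1), a kinase of the spliceosome, had 16 transcripts within 3940 nt on chromosome 4, from 33953810 to 33957749 on the minus strand. It had 3 skipped exons and 4 retained introns, and 11 of its transcripts had MSTRG identifiers.

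**Figure D1:**
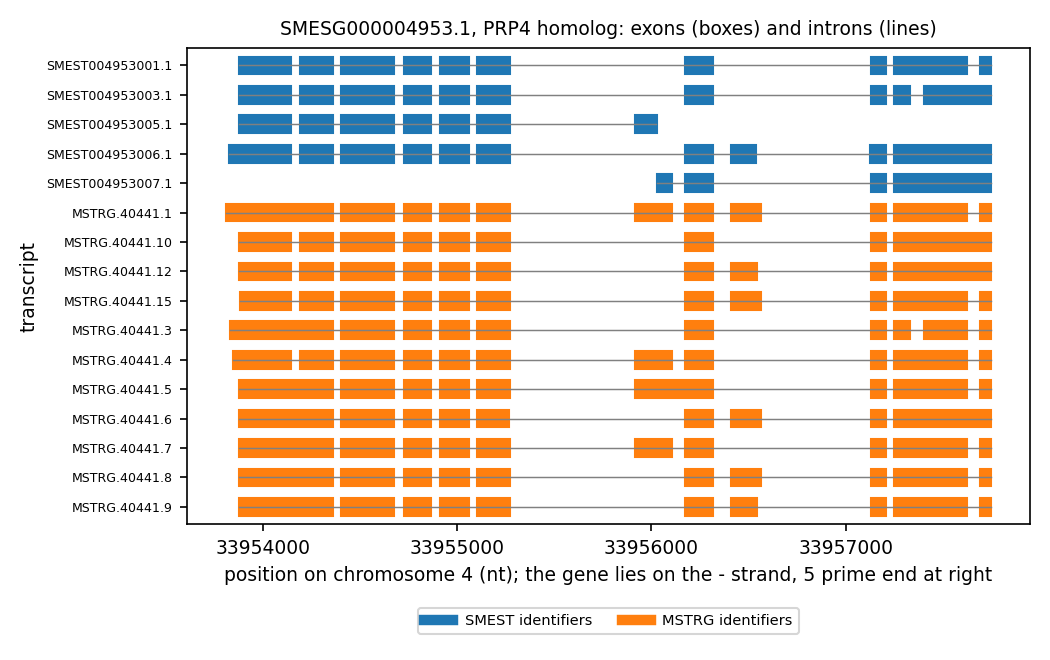
Exons (boxes) and introns (lines) of the 16 transcripts of SMESG000004953.1, the PRP4 homolog, against position on chromosome 4 in nt. The 5 transcripts with SMEST identifiers and the 11 with MSTRG identifiers are coloured apart, and transcripts of both kinds vary in the exons near the middle of the locus.

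The longest transcript, 48466 nt with up to 81 exons in the locus, belonged to Titin (SMESG000005752.1), the giant elastic protein of muscle. A second locus named Microtubule-actin cross-linking factor 1 (SMESG000016745.1) reached 37460 nt. MSTRG.25954, named after General transcription factor II-I repeat domain-containing protein 2, reached 36059 nt with up to 9 exons, and SMESG000062860.1, named Esterase OVCA2, 29789 nt, also with up to 9 exons. The longest spans were those of Receptor-type tyrosine-protein phosphatase F (SMESG000041927.1), a cell adhesion receptor, at 247534 nt, Nidogen-2 (SMESG000077687.1), a basement membrane protein, at 204355 nt, and Actin-11 (SMESG000041540.1) at 200069 nt. The locus named Actin-11 had up to 22 exons and carried no Pfam domain. SMESG000039966.1, without a protein name, spanned 175611 nt, and SMESG000056370.1, Pleckstrin homology domain-containing family G member 5, 149880 nt. Fibrillin-1 (SMESG000076582.1), an extracellular matrix protein, had the most exons, 102. It was followed by Ryanodine receptor 1 (SMESG000000645.1), a calcium release channel, with 97. Mucin-5AC (SMESG000041532.1), a secreted gel-forming protein, had 86 exons, and SMESG000026263.1, which carries a dynein heavy chain domain, 84.

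Loci differed with the identifier and source in the file. The 16529 SMESG loci with source StringTie had a median of 5 exons, a longest transcript of 1846 nt and a span of 6443 nt. The 4011 MSTRG loci had medians of 2 exons, 660 nt and 873 nt, and the 4713 SMESG loci with source NewAnnot_Sep23 had 1 exon, 1139 nt and 1410 nt. More than 1 transcript was found in 47.0%, 9.40% and 7.49% of the 3 classes in that order. Single-exon loci made up 12.7%, 47.0% and 50.7%, and protein names were carried by 65.8%, 35.3% and 38.9%. Names of the transposable element list, such as transposases and reverse transcriptases, stood on 585 MSTRG loci, or 14.6% (13.5 to 15.7%), and on 343 SMESG StringTie loci, or 2.08% (1.87 to 2.30%). MSTRG.8661, named after a transposase-like protein, had the most transcripts of its class, 9. In the NewAnnot_Sep23 class this was SMESG000062155.1 with 6, named after TTLL8, a tubulin-modifying enzyme. The 12 mitochondrial genes, ATP6 among them, had 1 transcript each.

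MSTRG loci had -3 exons relative to SMESG StringTie loci in the median, and the length and span differences were -1186 nt (95% bootstrap interval -1213 to -1149) and -5570 nt (-5761 to -5312). Each adjusted permutation p was 1e-05, the smallest the permutations give. Within SMESG loci, 9464 further transcripts with MSTRG identifiers were placed in 6055 loci. The file does not say which libraries gave rise to a locus.

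**Figure D2:**
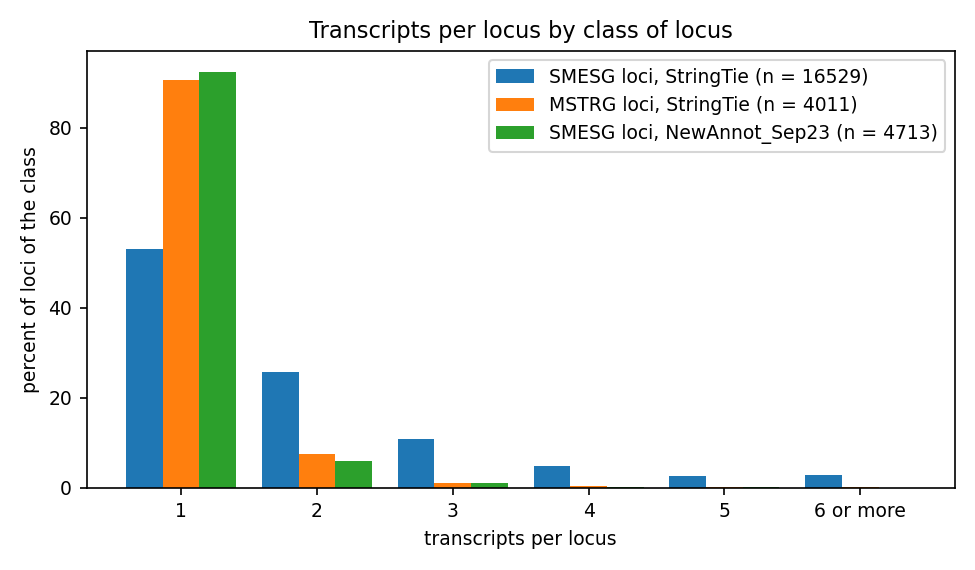
Percent of loci (vertical axis) by transcripts per locus (horizontal axis) for the 3 classes of nuclear loci, with no error bars. Loci with 1 transcript dominate the MSTRG and NewAnnot_Sep23 classes, while 47.0% of SMESG StringTie loci have more than 1.

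Introns fell into a short and a long group. Of the distinct introns, 44.6% measured 40 to 60 nt, 7.32% measured 100 to 500 nt and 41.8% were longer than 500 nt. The most frequent length was 46 nt, with 4615 introns, and the median was 86 nt. Introns shorter than 100 nt made up 50.9% (50.6 to 51.1%). In 11018 genes with at least 3 introns, 67.4% of first introns (66.5 to 68.3%), 49.7% of middle introns (49.3 to 50.1%) and 48.7% of last introns (47.8 to 49.6%) were shorter than 100 nt. First, middle and last follow the annotated 5 prime to 3 prime order of the longest transcript. These shares were not tested against each other.

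**Figure D3:**
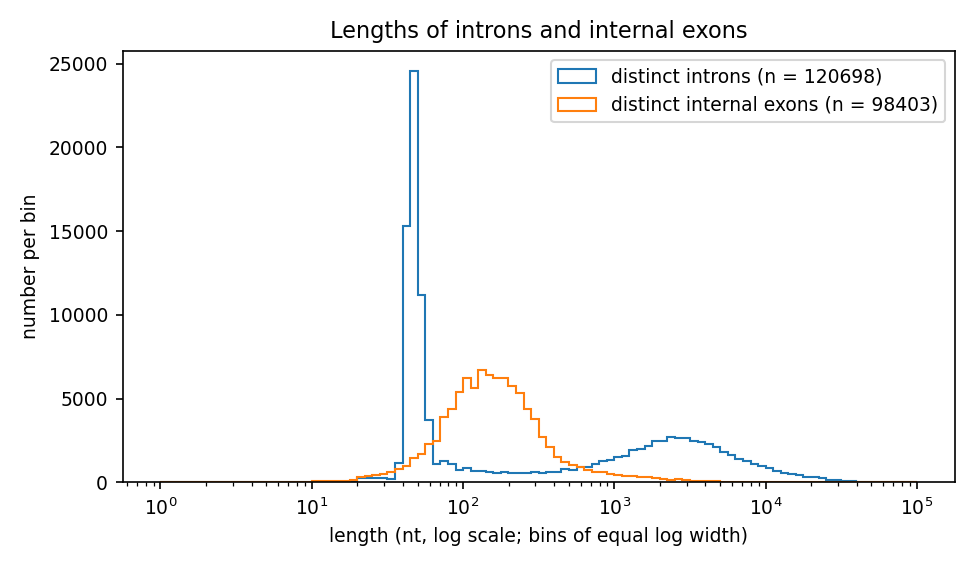
Number of distinct introns and distinct internal exons per bin (vertical axis) against length in nt on a log scale. Introns form a narrow group around 46 nt and a broad one of longer than 500 nt, and internal exons lie between them with a median of 153 nt.

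Retained introns were the most frequent of the 6 kinds of event called. There were 6944 in 4280 genes, against 1833 alternative acceptors in 1492 genes, 1717 skipped exons in 1239 genes and 1594 alternative donors in 1301 genes. Alternative first exons numbered 537 in 363 genes and alternative last exons 314 in 240 genes. Of the genes with more than 1 transcript, 75.5% had at least 1 of the 6 kinds. Retained introns had a median length of 50 nt, and 82.6% of them (81.7 to 83.5%) were shorter than 100 nt. An exon that covered several introns gave an event for each of them, so the kinds are not counted in like units. Coordinates alone do not tell regulated retention from RNA that was not yet spliced. Acceptor pairs were most often 3 nt apart, in 246 of 1833 cases or 13.4% (11.9 to 15.1%), and donor pairs most often 6 nt apart, in 109 of 1594 cases, or 4 nt apart, in 108.

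Skipped exons were multiples of 3 nt more often than constitutive exons, 73.9% (71.8 to 75.9%) against 43.0% (42.5 to 43.5%). The difference was 30.9 percentage points (95% interval 28.5 to 33.2, bootstrap over 6249 genes). Skipped exons were shorter, with a median of 78 nt against 146 nt. Exons of at most 27 nt made up 17.1% of skipped exons (294 of 1717) and 1.11% of constitutive exons (474 of 42577). Of these, 88.4% and 67.9% were multiples of 3 nt. The difference rose to 43.7 points among events between transcripts with SMEST identifiers, and was 28.2 points among exons of 28 nt or longer.

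**Figure D4:**
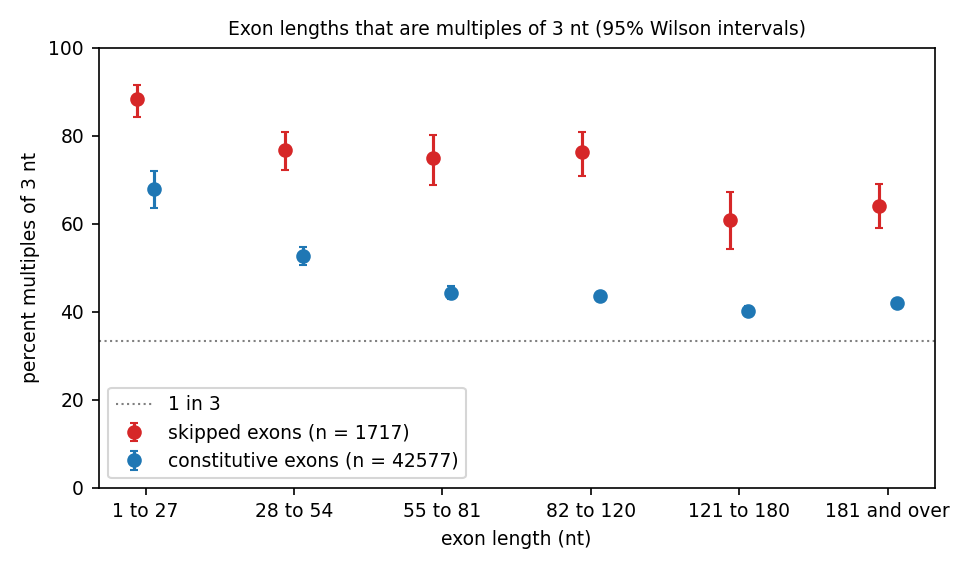
Percent of exons whose length is a multiple of 3 nt (vertical axis) by exon length in nt (horizontal axis), for skipped and constitutive exons, with 95% Wilson intervals; the dotted line marks 1 in 3. Skipped exons lie above constitutive exons in every length range, with 88.4% against 67.9% at up to 27 nt.

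Genes with a name that matched the kinase, phosphatase and GTPase regulator patterns had more transcripts than random named genes of like exon number. The 1113 genes had a mean of 2.39 transcripts against 2.07, a difference of 0.315 (adjusted permutation p = 0.0015, from 10000 random lists). The list takes in SMESG000040665.1, through 1 of its 8 names, and SMESG000080852.1, named a kinase-binding protein and not a kinase. The 252 splicing factor genes had 1.81 against 1.58 transcripts (difference 0.229, adjusted permutation p = 0.009). They were led by the PRP4 homolog and by SMESG000041611.1, an arginine/serine-rich splicing factor with 10 transcripts. The full name of the PRP4 homolog, a serine/threonine-protein kinase, also matches the kinase patterns, so that locus counts in the kinase list as well. Both lists also passed when matched on genomic span, with differences of 0.243 (adjusted permutation p = 0.003) and 0.251 (adjusted permutation p = 0.021). Names of all transcripts were searched, so genes with more transcripts had more chances to enter a list, which can raise these differences. With the name of the longest transcript alone, the kinase list held 1043 genes and its difference fell to 0.181 (adjusted permutation p = 0.003). The splicing factor difference was then 0.208 (adjusted permutation p = 0.019). With MSTRG transcripts alone counted, the kinase difference was 0.151 (adjusted permutation p = 0.001). The splicing factor list did not pass without the PRP4 homolog, at 0.176 (adjusted permutation p = 0.055), or with MSTRG transcripts alone counted, at 0.0837 (adjusted permutation p = 0.27). Without the PRP4 homolog but with random lists drawn from all genes it passed, at 0.259 (adjusted permutation p = 0.0015). That pool holds unnamed genes, which could not enter a list, and its random mean was lower, 1.49 against 1.57 for named genes. The pass thus rests in part on the pool.

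The 407 neural genes had 2.16 against 1.96 transcripts (difference 0.206, adjusted permutation p = 0.0442). Leading members were a voltage-dependent L-type calcium channel (SMESG000000524.1) with 12 transcripts and potassium voltage-gated channel subfamily H member 3 (SMESG000017882.1) with 10. Matched on genomic span instead, the neural difference was -0.192 (adjusted permutation p = 0.123), and the neural list failed to pass in 6 of 8 alternatives. The 357 cilia genes had fewer transcripts, 1.73 against 2.01 (difference -0.283, adjusted permutation p = 0.0015). The members named by the rule, which takes those with most transcripts, were axonemal dynein heavy chains, motors of cilia. These were SMESG000056575.1 with 10 transcripts and SMESG000004475.1 with 7, so they do not typify the list. A Pfam tubulin domain stood in 127 genes with a mean of 1.504 transcripts, 54 of them NewAnnot_Sep23 loci. The word tubulin is among the patterns of the cilia list, so every gene with it in a protein name entered that list. How many of the 127 genes entered the cilia list was not counted, and the list was not tested without them. Among StringTie loci alone the cilia difference was -0.342 (adjusted permutation p = 0.002). Matched on span, the cilia difference was -0.145 (adjusted permutation p = 0.123).

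The other 11 lists did not pass. Epidermis and secretory cells, led by laminin and by SMESG000076350.1 with 14 transcripts, had a difference of 0.464 (adjusted permutation p = 0.051), which rested on the laminin locus: without it the difference was 0.0976 (adjusted permutation p = 0.643). With the name of the longest transcript alone, laminin included, it was 0.493 (adjusted permutation p = 0.042). Transcription factors had 0.118 (adjusted permutation p = 0.142). Wound response had 0.144 (adjusted permutation p = 0.423). Transposable elements had 0.0252 (adjusted permutation p = 0.517). Of its 1147 genes 585 are MSTRG loci, against 1415 of all 14124 named genes, so a count of MSTRG transcripts alone does not test this list. With random lists drawn from all genes, as first run, 7 lists passed: these 4, epidermis and secretory cells at 0.530 (adjusted permutation p = 0.017), transcription factors at 0.186 (adjusted permutation p = 0.009) and transposable elements at 0.118 (adjusted permutation p = 0.001). Without laminin, epidermis and secretory cells did not pass there either, at 0.159 (adjusted permutation p = 0.474). With the member with most transcripts left out of each list, the other lists of these 7 still passed there. Differences were -0.170 for neoblasts and proliferation, -0.0110 for positional control, -0.0340 for muscle, -0.103 for intestine, -0.0495 for protonephridia and transport, -0.0787 for ribosomal proteins and -0.0107 for oxidative phosphorylation, with adjusted permutation p from 0.506 to 1.

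Members of the lists that did not pass included proliferating cell nuclear antigen (SMESG000046293.1), the DNA polymerase clamp, with 8 transcripts, and the PCNA-interacting partner (SMESG000004659.1) with 9. The first of these loci carries 2 protein names, and 7 of its 8 transcripts have MSTRG identifiers. Its longest transcript measured 26992 nt, and whether all 8 belong to the named gene was not examined. The wound response list was led by the loci SMESG000027094.1 and SMESG000055134.1 with 10 transcripts each, both named JNK-interacting protein 3, a kinase scaffold and not a Jun factor. Positional control was led by fibroblast growth factor receptor 3 (SMESG000051694.1) and Netrin-1 (SMESG000050895.1), an axon guidance cue, with 7 each. Myosin-16 (SMESG000056451.1) had 10 transcripts, and the calcium channel above also entered the muscle list. Cubilin (SMESG000080965.1), an endocytic receptor, had 12 and the sodium-driven chloride bicarbonate exchanger (SMESG000024335.1) 11. For the intestine list, lysosomal protective protein (SMESG000029163.1) had 9 and a patatin-like phospholipase (SMESG000000836.1) 8. Some members do not do what their list is named for. Ribosomal proteins were led by S6 kinase (SMESG000046977.1), which is not a ribosomal protein, with 6 transcripts. RACK1 (SMESG000069927.1), named a small ribosomal subunit protein, followed with 5. Oxidative phosphorylation was led by an amidotransferase (SMESG000046991.1) with 8 and the complex I assembly factor NDUFAF5 (SMESG000038413.1) with 5. An actin-binding LIM protein (SMESG000080177.1) and Zinc finger protein 106 (SMESG000052755.1), with 7 each, led the transcription factors. The transposable element list was led by SMESG000040665.1 and by SMESG000000765.1 with 13, whose other name is Obg-like ATPase 1.

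**Figure D5:**
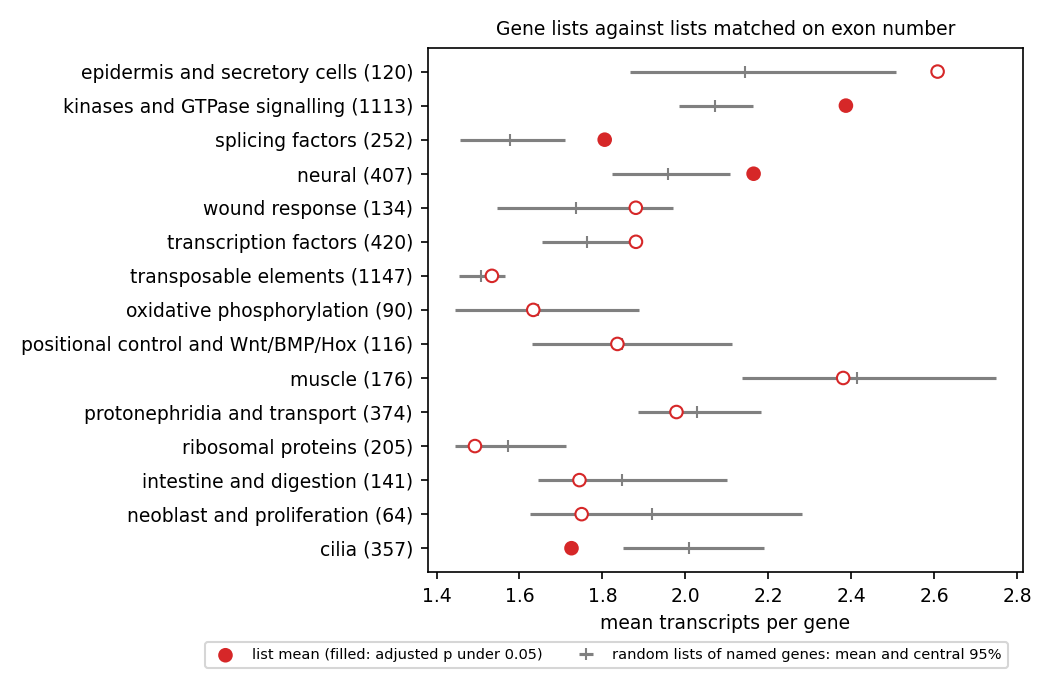
Mean transcripts per gene (horizontal axis) of the 15 lists, with gene numbers in parentheses; grey bars are the mean and central 95% of 10000 random lists of named genes matched on exon number. Filled points, for kinases, splicing factors, neural genes and cilia, have an adjusted p under 0.05; matched on span, the neural and cilia lists do not.

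The longest mRNA of each gene had a median of 1548 nt and ncRNA features 70 nt, a difference of 1478 nt (1458 to 1500; permutation p = 1e-05). Matched on exon number, that is with single-exon genes alone, the difference was 833.5 nt (permutation p = 1e-05). No mRNA in the annotation was shorter than 200 nt, while the largest ncRNA classes, misc_RNA and tRNA, had medians of 60 and 72 nt. The direction was thus largely fixed beforehand, and the p-values of this comparison add no evidence to the sizes. The ncRNA set included 4752 misc_RNA features, of which 4489 carry the name of a reovirus 60-mer, and 4298 tRNA, 2287 rRNA, 1042 miRNA, 408 RNase P, 141 snRNA and 69 snoRNA features, and 40 features of SRP RNA, the RNA of the signal recognition particle. These are the class names in the file, and feature names do not always match them. Planarian names stood on 2566 features, or 19.1%, and the length difference from these alone was 1471 nt (permutation p = 1e-05). The most frequent name in the rRNA class was an unclassified non-coding RNA of Caenorhabditis elegans. Of miRNA features, 734 carried planarian names in 89 families, of which 57 had 1 copy, while the mir-753 family had 510 copies and mir-2147 had 62. All 40 SRP RNA features lay on chromosome 3 between 46027232 and 46061856.

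Genes were denser on chromosomes 3 and 4 than on the longer chromosomes 1 and 2, at 31.2, 30.9, 37.8 and 46.4 per Mb on chromosomes 1 to 4. Features of ncRNA stood at 15.2, 18.0, 14.8 and 38.3 per Mb. MSTRG loci made up 15.1%, 17.0%, 17.7% and 11.8% of genes. The 3 classes of loci were spread unevenly over the 4 chromosomes (chi-square 66.6, permutation p = 1e-05), with a Cramer's V of 0.0363.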

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

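All results in this part were chosen after the file was seen, and the test of strand shares was chosen after its result was known. The design has no group that gives a biological explanation to test.

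Signals in records outside the comparisons of genes came first from 4489 ncRNA features that carry the name of a 60-mer RNA of a mammalian reovirus, an RNA virus of vertebrates. Viral insertions at a few sites are argued against, since the 10 densest windows of 1 Mb held 5.17% of the features (95% interval 4.56 to 5.86%) and 689 of 766 windows held at least 1. Matches to interspersed genome sequence are a candidate explanation that these values do not test. Of the features, 50.1% lay on the plus strand (48.6 to 51.5%), and all 4 chromosomes carried them. Any source without a strand preference would give such a split. A preference for the strand of the annotated gene is argued against within introns. There, 1086 features lay inside genes of the same strand and 1092 inside genes of the opposite strand, a ratio of 0.995 (0.914 to 1.08). For the few on exons, 101 against 102, such a preference stays open, with a ratio of 0.990 (0.761 to 1.31). Positions without read values do not tell whether the features are transcribed with those genes, so that explanation stays open.

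Features of misc_RNA, the class that holds all of these, lay in introns in 49.2% of cases against a mean of 25.3% in 1000 rotations, and on same-strand exons in 2.17% against 4.30% (adjusted circular permutation p = 0.00564 for both).

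All 10 mir-749 precursors overlapped the 10 features of the selenocysteine tRNA (SEC-TCA) on the same strand, with ends 0 to 3 nt apart, on chromosome 2 between 225433886 and 225880531. After features that overlap on the same strand were merged, 1686 of 10835 places held more than 1 class of ncRNA, most often misc_RNA with rRNA at 1093 places.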

How the results depend on the processing

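Chosen after seeing the data were the list alternatives other than span and intron chains, the planarian-named ncRNA alternative, and all alternatives for loci by identifier, short introns, exon frame and antisense genes. Of 148 alternatives over 25 results, 114 kept direction and side of the threshold or stayed within the interval. Many of these belong to lists that did not pass in the main version and stayed so. The 200 nt minimum removed no transcript, and merging genes leaves the transcript number and multi-exonic share unchanged by construction. The count thus does not measure how stable the lists that passed were. Where no reason is given, the cause was not tested. The share of genes with more than 1 transcript was 32.7% with equal intron chains counted once and 44.9% among multi-exonic genes. The share of short introns was 51.4% over each intron of each transcript. The frame difference was 43.7 points for SMEST events and 28.2 for exons of 28 nt or longer, and antisense genes were 0.318% of multi-exonic genes. List differences in transcripts per gene that changed sign or crossed the threshold were as follows; others moved without doing either, such as positional control at -0.278 and protonephridia at -0.141 when matched on span. Matched on genomic span they were muscle 0.233, neural -0.192, epidermis -0.0193, ribosomal proteins 0.0919, transposable elements -0.0478, oxidative phosphorylation 0.131 and cilia -0.145. With equal intron chains counted once neural was 0.190 (adjusted permutation p = 0.0757). With leading names positional control was 0.0272 and transposable elements -0.0440. With lists from all genes they were positional control 0.0439, muscle 0.0584, ribosomal proteins 0.0179, oxidative phosphorylation 0.0738, epidermis 0.530, transposable elements 0.118 and transcription factors 0.186. With the name of the longest transcript neural was 0.142, epidermis 0.493, which passed, and transposable elements -0.0149. Without the member with most transcripts, which lowers a list's mean by construction, neural was 0.186 and splicing factors 0.176. Among StringTie loci neural was 0.204. With MSTRG transcripts alone, which count fewer transcripts per gene, they were neural 0.0749, splicing factors 0.0837, epidermis -0.0455, oxidative phosphorylation 0.0365 and transposable elements 0.339, a value raised by construction by the MSTRG loci in that list; kinases had 0.151. Of the 9 versions, kinases passed in all and cilia in all but the span-matched one. Splicing factors passed in all but the MSTRG one and the named-gene one without the PRP4 homolog. The alternatives for read support, reference overlap, splice-site dinucleotides and untranslated or coding lengths were not run. No paired analysis was possible because each group had 1 library. Depth was unknown, and rare transcripts below the reach of these libraries limit every count.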

Other observations

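The observations and hypotheses in this part were chosen after the file was seen. Repeated tRNA genes stood in arrays. On chromosome 1, 85 tRNA features for threonine (AGT) had a median gap of 186 nt between positions 261535254 and 261624897. On chromosome 4, 57 for serine (CGA) had a median gap of 212 nt, between 13396242 and 13415776. The U3 snoRNA, which acts in rRNA processing, had 69 copies, 56 of them on chromosome 2, and U2 spliceosomal RNA had 32, all on chromosome 1. Features of tRNA lay between genes in 91.6% of cases, against a mean of 65.2% in 1000 rotations (adjusted circular permutation p = 0.00564). Planarian-named miRNA precursors of different families formed 10 clusters on 1 strand with gaps of at most 1000 nt, among them let-7 with mir-36 on chromosome 1, and mir-71 with mir-2 on each of the 4 chromosomes.

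Among Pfam domains, protein kinases (Pkinase) stood in 441 genes with a mean of 2.44 transcripts, and ankyrin repeats (Ank_2) in 224 genes with 3.23. Histone genes numbered 61, of which 59.0% had a single exon. Exons of opposite-strand genes overlapped in 74 pairs, 148 genes or 0.586% (0.499 to 0.688%). The number of minus-strand genes in such a pair was 74, against 1959 to 2178 in 100 rotations. The share was the same with at least 50 bases of overlap required. MSTRG loci made up 66 of the 148 genes, or 1.65% of their class, against 0.436% of SMESG StringTie loci and 0.212% of NewAnnot_Sep23 loci. How the annotation was built or filtered is not known, so the low number cannot be read as biology. Its cause was not tested.

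MSTRG loci had fewer exons than SMESG StringTie loci. Names of the transposable element list do not account for the whole difference among named loci. With them left out, the median difference was still -4 exons (95% interval -4 to -4, 830 and 10535 loci). That list rests on name patterns and can miss other mobile element names, so mobile elements as a cause stay open. Fragments of neighbouring genes may contribute and stay open: a SMESG gene lay within 1000 nt on the same strand for 129 MSTRG loci and on the opposite strand for 119, a ratio of 1.08 (0.846 to 1.38). That interval lies below the bound set in advance for fragments as the cause and reaches above the bound set for the opposite. No biological explanation was tested.

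Skipped exons were multiples of 3 nt more often than constitutive exons. Exon length as the whole cause is argued against, since after weighting constitutive exons to the lengths of skipped ones the difference was 24.9 points (22.3 to 27.4). So is a small number of genes with many skipped exons, since with every gene weighted equally it was 31.1 points (28.7 to 33.6). Selection of transcripts for an open reading frame during annotation may contribute and stays open: retained introns of up to 100 nt exceeded other such introns by 2.67 points (1.26 to 4.01), with 35.2% against 32.5% multiples of 3 nt. That interval lies below the bound set in advance for this cause and reaches above the one set for the opposite. Distances of alternative donor and acceptor pairs were multiples of 3 nt in 53.4% and 55.4% of cases, above 1 in 3. No bound was set for these shares, and they do not tell selection during annotation from other causes. No biological explanation was tested.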
